A study of Homo sapiens with 19 samples.

How the data were processed

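Total RNA, extracted with Trizol and labelled with biotin, from 19 xenograft samples was hybridised to 1 Affymetrix gene array each. The deposited values are on a log2 scale and are given for 33297 probe sets in 19 columns, 1 per sample. The authors' processing notes name RMA and Partek, without settings or versions. RMA usually corrects background, normalizes between arrays and summarises the probes of a set. The array medians (4.66 to 4.84) and 95th percentiles (8.82 to 9.04) were checked and fit a log2 scale of intensity without centring on controls. Scanner files and detection calls were not used here. The human probes may also bind RNA of the mouse host, which could not be separated in these values.

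Of the probe sets, 21236 are listed with genes, 19181 of them with 1 symbol and 2055 with several, and 12061 are not listed. Probe sets with 1 symbol were kept, and where a symbol had more than 1 probe set (895 genes) the set with the highest mean over all arrays was taken, which left 17958 genes. Genome coordinates were not used here. Samples were grouped by the titles into 6 groups: PE4 control, PE4 estrogen, PT12 control, PT12 estrogen, PT12 withdrawal and PT12 tamoxifen.

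All 19 arrays entered 1 limma fit of the 6 group means (limma 3.58.1 in R 4.3.3) with its eBayes moderated test (prior degrees of freedom 3.89, residual degrees of freedom 13). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, with two-sided tests. The 9 comparisons were estrogen against control in each xenograft, the difference between these effects, withdrawal against estrogen and control, tamoxifen against estrogen, control and withdrawal, and the untreated xenografts against each other. Replicate numbers in the titles were not used as a block. Over all groups of a xenograft, arrays with the same number were not clearly more alike than others. The median correlation of their deviations from the group means was -0.164 in PE4 and -0.0193 in PT12, against 0.0378 and -0.0414 for different numbers. Between PT12 control and withdrawal, however, pairs with the same number (0.111 to 0.176) all exceeded those with different numbers (-0.121 to -0.00194). A total of 26 gene lists with 556 members, of which 508 were measured, were tested with camera of limma at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. Of the 72 results past the threshold none passed it with an estimated correlation, and 21 did with fry, which tests whether a list moves on balance but not against other genes. The comparisons, tests, lists and rules for naming genes were fixed before the data were examined. Named were the 10 genes with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap between the groups (5 each way for the difference between xenografts, without that condition), a panel of ESR1, PGR, GREB1, TFF1, CXCL12, MYC, MKI67, KRT5 and CCND1, and up to 4 members of each list described, called ones first. 1 further gene of that panel was not analysed here. Left out were probe sets with no symbol or several, XIST and Y-linked genes, and genes with only clone identifiers as names.

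Overlaps of calls were compared with the number expected for independent calls. For comparisons that share arrays, 50 data sets without effects were simulated from the fitted residual spread. The estrogen arrays were also divided in 6 ways, so that each comparison used other estrogen arrays. The fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold: it recovered between 61 and 91 of the first and between 96 and 100 of the second, with 7 to 17 false calls. In 9 simulations, camera called a list moved by 1.5-fold in 9 and an unmoved list in 0. The noise of the simulated genes was drawn independently. These simulations therefore do not give the error rates where genes vary together, as members of a list may. Whether the arrays of 2 groups overlapped on a list called by camera was read from the mean level of its members in each array, an addition after seeing the data. A list counted as reversed where the direction given by camera turned. Alternatives tried were a replicate block, only the compared groups in the fit, eBayes with trend and robust options, array weights, arrays centred on their medians, quantile normalization, subtraction of the 5th percentile of each array with 16 added before log2, genes below the median level left out, the mean of the probe sets of a gene, all probe sets tested, and each array left out in turn. Added after seeing the data were the averaging of PE4 estrogen arrays 1 and 3, the interquartile range of each array as a covariate, and PT12 estrogen array 1 and withdrawal array 3 left out together. The comparison of calls shared by estrogen and tamoxifen was also added then. For every count, other splits of the same arrays (100 drawn where there were more) were fitted in the same way.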

Results

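Gene expression was measured by microarray in total RNA from PE4 and PT12, 2 luminal human breast cancers kept as xenografts in immunodeficient mice, with the aim, per the series title, of following the estrogen receptor. PE4 was sampled without treatment (control, 3 arrays) and after estrogen (3 arrays). PT12 was sampled as control (3 arrays), after estrogen (4 arrays), after estrogen withdrawal (3 arrays) and after tamoxifen (3 arrays), an estrogen receptor modulator used as a breast cancer drug. The labels give no dose or time, do not say whether tamoxifen was given together with estrogen, and do not say whether the arrays of a group come from separate animals, so all p-values measure only the spread between arrays. Array medians lay between 4.66 and 4.84 on the log2 scale and 5th percentiles between 2.33 and 2.53. The number of arrays limits the precision of every value. The interquartile range of an array was 3.02 ± 0.0595 (SD, n = 3) in PE4 controls, 3.04 ± 0.00917 (n = 3) in PE4 estrogen. It was 2.52 ± 0.0704 (n = 3) in PT12 controls, 2.76 ± 0.136 (n = 4) in PT12 estrogen, 2.37 ± 0.121 (n = 3) in withdrawal and 2.67 ± 0.124 (n = 3) in tamoxifen. Of the variance over all genes, 66.1% lay along the first principal component and 9.5% along the second. Differences below are on the log2 scale with the standard error of the limma fit, and adjusted p-values are over all 17958 genes tested. Each gene named as one of the largest rises or falls had arrays of its groups that did not overlap, so that every array showed the direction. Differences are not exact in size where 1 of the group means lay under 3.43, the lowest 25th percentile of an array. This holds for TCN1, PVALB, POF1B, MS4A1 and FCRL1 in PE4 controls, TARP in both PE4 groups, TMEM45A in PE4 estrogen, PGR in every PT12 group, GRPR in PT12 controls, ZNF804B in PT12 controls and estrogen, TARP, DPPA2 and CLCA2 in PT12 estrogen, KRT222 in withdrawal, and ZNF415, NANOGNB and GSTA5 in tamoxifen arrays. Of the 65 gene list results past the threshold between 2 groups, 32 had arrays that overlapped between the groups in the mean level of the list.

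The first question was what estrogen changed in PE4 (3 estrogen arrays against 3 controls). SULF1, which edits heparan sulfate at the cell surface, rose most, from 5.12 ± 0.76 to 8.92 ± 0.67 (mean ± SD), a difference of 3.80 ± 0.30 (adjusted p = 2.63e-06). PGR, the progesterone receptor and a classical estrogen target, rose from 5.66 ± 0.64 to 7.70 ± 0.27, a difference of 2.03 ± 0.24 (adjusted p = 1.13e-04). BMPR1B, a receptor for bone morphogenetic proteins, showed the largest fall, from 9.27 ± 0.71 to 4.84 ± 0.10 (-4.43 ± 0.25, adjusted p = 4.62e-08), and the angiotensin receptor gene AGTR1 fell from 8.86 ± 0.82 to 5.54 ± 0.53 (-3.32 ± 0.29, adjusted p = 5.38e-06). The other large rises were ZNF804B (2.81), C6orf141 (2.49), TAFA2 (2.48), the carbonic anhydrase gene CA2 (2.39), the glutamate receptor gene GRIK3 (2.29), the prostaglandin transporter gene SLCO2A1 (2.28), AGR3 (1.99) and ZBTB18 (1.89). The other large falls were AARD (-3.12), TPRG1 (-3.05), NRIP3 (-2.80), KRT40 (-2.73), SCUBE2 (-2.73), LIN7A (-2.68), LRRN1 (-2.46) and LURAP1L (-2.37). The chemokine gene CXCL12 rose by 1.66 ± 0.30 (adjusted p = 0.00581). Other genes of the fixed panel did not pass: GREB1 differed by 0.98 ± 0.74 (adjusted p = 0.999), MYC by 0.98 ± 0.27 (0.103), TFF1 by -0.85 ± 0.77 (0.999), the estrogen receptor gene ESR1 by -0.45 ± 0.27 (0.858), CCND1 by -0.27 ± 0.39 (0.999), the proliferation marker MKI67 by 0.14 ± 0.37 (0.999) and KRT5 by 0.04 ± 0.14 (0.999).

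Among gene groups in PE4, ribosome biogenesis was higher with estrogen (median difference 0.44 over 27 members, camera adjusted p = 1.50e-11, adjusted p = 0.0809 with an estimated correlation). None of its members passed over all genes in limma, and 8 rose when adjusted over the list alone. The interferon response list was lower (median -0.39 over 35 members, camera adjusted p = 2.62e-11, adjusted p = 0.103 with an estimated correlation). Its members IFI27 (-1.41 ± 0.33) and OAS1 (-1.29 ± 0.22) fell, 33 did not pass, and 10 fell when adjusted over the list alone. The list of estrogen-induced genes was higher (median 0.10 over 49 members, camera adjusted p = 0.00712, adjusted p = 0.974 with an estimated correlation). PGR, AGR3, CXCL12 and STC2 rose, 45 members did not pass, and 9 rose and 1 fell when adjusted over the list alone. With array weights its median was -0.0206 and camera no longer called it (adjusted p = 0.152). The hypoxia list was also higher (median 0.18 over 25 members, camera adjusted p = 0.0499, adjusted p = 0.974 with an estimated correlation), with ADM (0.86 ± 0.19) as its only member that rose, also when adjusted over the list alone. Over 19 alternatives the median of this list ranged from 0.0203 to 0.314, and it passed in 11. PE4 estrogen array 3 lay within the controls on the hypoxia list (0.506 against 0.457 to 0.716, with 0.725 and 1.1 in arrays 1 and 2) and on the estrogen-induced list (0.438 against 0.257 to 0.475). In all, 235 genes passed in limma, 103 higher and 132 lower, 59 of them at least 2-fold higher and 70 at least 2-fold lower. The count was 1043 with array weights and 102 with dimmer genes left out. Estrogen arrays 1 and 3 were very similar (r = 0.9957, against 0.9885 and 0.9881 with array 2). They received the highest weights of all arrays (3.98 and 3.54), so the count of 1043 may lean on that likeness.

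In PT12 (4 estrogen arrays against 3 controls), the estrogen receptor target GREB1 rose from 5.30 ± 0.79 to 8.08 ± 0.95 (mean ± SD), a difference of 2.77 ± 0.69 (adjusted p = 0.0289). EGLN3, a prolyl hydroxylase of the hypoxia pathway, rose most, from 4.91 ± 0.53 to 7.95 ± 0.76 (3.04 ± 0.60, adjusted p = 0.0111). The small GTPase gene RAB31 rose by 2.77 ± 0.36 (adjusted p = 0.00143). CPB1, which encodes a carboxypeptidase, showed the largest fall, from 9.97 ± 0.20 to 5.79 ± 1.33 (-4.18 ± 0.90, adjusted p = 0.0167). IGFBP5, a binding protein of insulin-like growth factors, fell from 8.11 ± 0.28 to 5.37 ± 0.21 (-2.74 ± 0.32, adjusted p = 5.24e-04). The other large rises were ST8SIA6 (2.63), MPPED2 (2.58), TMEM45A (2.41), TUSC3 (2.36), GLRA3 (2.28), LMO3 (2.22) and CASP14 (2.19). The other large falls were PVALB (-3.71), TARP (-3.54), PPFIA2 (-3.00), GRIK1-AS2 (-2.99), SPAM1 (-2.70), SNORA60 (-2.65), SNORA14B (-2.13) and SERPINA6 (-2.08). TFF1 differed by 0.85 ± 0.72 (adjusted p = 0.507), CCND1 by 0.75 ± 0.37 (0.232), CXCL12 by 0.50 ± 0.28 (0.291), MYC by 0.24 ± 0.25 (0.604), MKI67 by 0.15 ± 0.35 (0.836), KRT5 by 0.17 ± 0.13 (0.478) and ESR1 by -0.19 ± 0.25 (0.682). PGR stood at 3.27 ± 0.31 with estrogen and 3.26 ± 0.13 without, below the 25th percentile of the arrays (3.43 to 3.76), and differed by 0.01 ± 0.22 (adjusted p = 0.983).

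**Figure D1:**
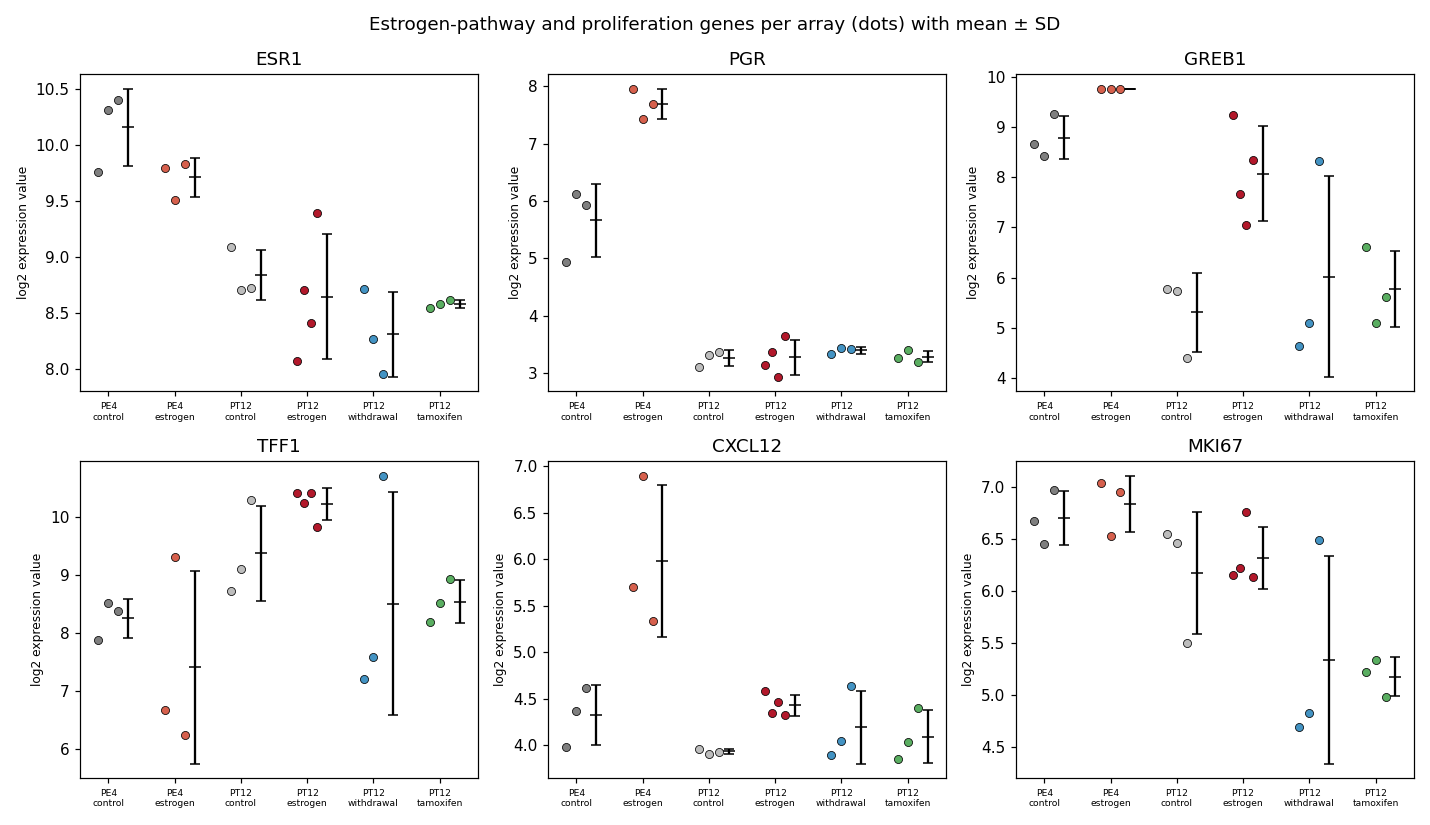
Log2 expression values (vertical axes) of ESR1, PGR, GREB1, TFF1, CXCL12 and MKI67 in each array (dots) by group, with the group mean and SD beside them. PGR stands at 7.70 ± 0.27 in PE4 with estrogen and at 3.27 ± 0.31 in PT12 with estrogen, and the third withdrawal array lies above the other withdrawal arrays for GREB1 and TFF1.

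The hypoxia list was higher with estrogen in PT12 (median 0.57 over 25 members, camera adjusted p = 6.64e-07). EGLN3, NDRG1 (1.94 ± 0.52), the glucose transporter gene SLC2A1 (1.71 ± 0.48) and VEGFA (1.49 ± 0.41) were among the 6 members that rose, and 11 rose when adjusted over the list alone. Of the 49 estrogen-induced genes, 5 rose, GREB1, NPY1R (1.75 ± 0.47) and RASGRP1 (1.53 ± 0.41) among them, and SERPINA1 fell (-1.67 ± 0.33), with 9 higher and 3 lower when adjusted over the list alone (median 0.44, camera adjusted p = 5.05e-04). The luminal identity list was higher (median 0.60 over 19 members, camera adjusted p = 5.05e-04), with ELF3 (1.58 ± 0.36) and MLPH (1.43 ± 0.33) past the test and 4 higher when adjusted over the list alone. Its mean level in estrogen array 3 (-0.532 from the mean of all arrays) lay within the range of the controls (-0.763 to -0.384), with 0.606, -0.0909 and 0.211 in arrays 1, 2 and 4. Of 35 interferon response members 6 rose, such as IFI6 (1.87 ± 0.47) and OAS3 (1.28 ± 0.24), and when adjusted over the list alone 7 rose and 1 fell (median 0.25, camera adjusted p = 0.00249). On this list estrogen array 1 (-0.101) lay within the controls (-0.125 to 0.164), with 0.348, 0.674 and 0.325 in arrays 2 to 4. The antigen presentation list was higher (median 0.32 over 20 members, camera adjusted p = 0.0421), although HLA-DRA fell (-1.34 ± 0.37) and TAP2 rose (0.88 ± 0.21), with 5 higher and 1 lower when adjusted over the list alone. On this list estrogen array 3 (-0.106) lay within the controls (-0.318 to 0.0613). The list of BCL2 family apoptosis genes was higher too (median 0.31 over 15 members, camera adjusted p = 0.0227), with MCL1 (0.78 ± 0.20) and BCL2L11 (0.74 ± 0.15) past the test, 2 also when adjusted over the list alone. For each of these lists the adjusted p = 0.664 with an estimated correlation. Over the alternatives the medians ranged from 0.315 to 0.647 for hypoxia, 0.0671 to 0.449 for estrogen-induced genes and 0.156 to 0.896 for luminal identity. They ranged from 0.0642 to 0.407 for interferon response, 0.234 to 0.486 for antigen presentation and 0.085 to 0.481 for BCL2 family apoptosis. Of 20 alternatives, antigen presentation passed in 7, BCL2 family apoptosis in 11 and the other lists in 16 to 18. In all, 1020 genes passed, 625 higher and 395 lower, 202 of them at least 2-fold higher and 104 at least 2-fold lower; quantile normalization gave 536 higher and 574 lower. The count rested on single arrays: it was 189 without control array 2, 367 without estrogen array 1, 1976 without estrogen array 3 and 551 without estrogen array 4, and it was 4 with the interquartile range as a covariate.

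Whether estrogen acted differently in the xenografts was tested as the PT12 difference minus the PE4 difference. BMPR1B fell in PE4 and rose by 0.84 ± 0.23 in PT12, a difference between xenografts of 5.26 ± 0.34 (adjusted p = 4.40e-07). LURAP1L likewise fell in PE4 and rose by 0.99 ± 0.19 in PT12 (3.36 ± 0.27, adjusted p = 5.16e-06). BMPR1B was already far lower in PT12 controls than in PE4 controls, so it had little room to fall in PT12. NR4A2, a nuclear receptor gene of the immediate early response, rose by 2.05 ± 0.33 in PT12 and differed by -1.34 ± 0.35 in PE4 (3.39 ± 0.49, adjusted p = 0.00189). In the other direction, SULF1 (-3.91 ± 0.42, adjusted p = 1.45e-04), TARP (-3.66 ± 0.70), IGFBP5 (-3.48 ± 0.47), AGR3 (-2.97 ± 0.49), ZNF804B (-2.75 ± 0.25) and PGR (-2.02 ± 0.33, adjusted p = 0.00476) had the lower difference in PT12. SERPINA3 (3.95 ± 0.78, adjusted p = 0.0193) and TMEM45A (3.82 ± 0.84, adjusted p = 0.0363) also passed. The differences of GREB1 (1.79 ± 1.01, adjusted p = 0.475), TFF1 (1.70 ± 1.06, 0.527), CXCL12 (-1.16 ± 0.40, 0.192), CCND1 (1.02 ± 0.54, 0.441), MYC (-0.75 ± 0.37, 0.395), ESR1 (0.25 ± 0.36, 0.827), KRT5 (0.13 ± 0.20, 0.841) and MKI67 (0.00 ± 0.51, 0.998) did not pass. The interferon response list had a median difference between xenografts of 0.72 (camera adjusted p = 3.59e-11, adjusted p = 0.196 with an estimated correlation). OAS1 (2.25 ± 0.30), OAS3 (1.82 ± 0.35), IRF9 (1.43 ± 0.32) and IFI35 (1.34 ± 0.32) were among its 5 members past the test, with 15 past it when adjusted over the list alone. Ribosome biogenesis had a median of -0.37 (camera adjusted p = 3.54e-05, adjusted p = 0.453 with an estimated correlation), with 2 members lower when adjusted over the list alone. In all, 209 genes passed, 132 with a higher and 77 with a lower difference in PT12. The count was 133 without PE4 control array 1, 115 without PE4 control array 3, 104, 138 and 110 without PE4 estrogen arrays 1, 2 and 3, 105 without PT12 control array 2, 133 without PT12 estrogen array 2, and 63 with the interquartile range as a covariate.

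Only 8 genes passed in both xenografts in the same direction, against 6.49 expected if the calls were independent. ANXA1 (1.71 ± 0.25 in PE4 and 1.55 ± 0.23 in PT12), FARP1, GALNT4, HEY2, LRIG1 and TOX3 rose in both, and the histone gene H2BC14 (-1.83 ± 0.36 and -1.64 ± 0.33) and MB21D2 fell in both. Another 5 passed in opposite directions: BMPR1B, CLIP4, LURAP1L, OAS1 and SIDT1. Across genes, which are not independent replicates, the differences correlated with r = 0.15. The count of shared genes was 3 without PE4 control array 1 or 2, 5 without PE4 control array 3, 5 without PE4 estrogen array 1, 4 without PE4 estrogen array 3, 5 without PT12 control array 1, 3 without PT12 control array 2, 5 without PT12 estrogen array 1 or 4, and 16 without PT12 estrogen array 3. It was 0 when only the compared groups entered the limma fits, where 155 genes still passed in PT12.

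**Figure D2:**
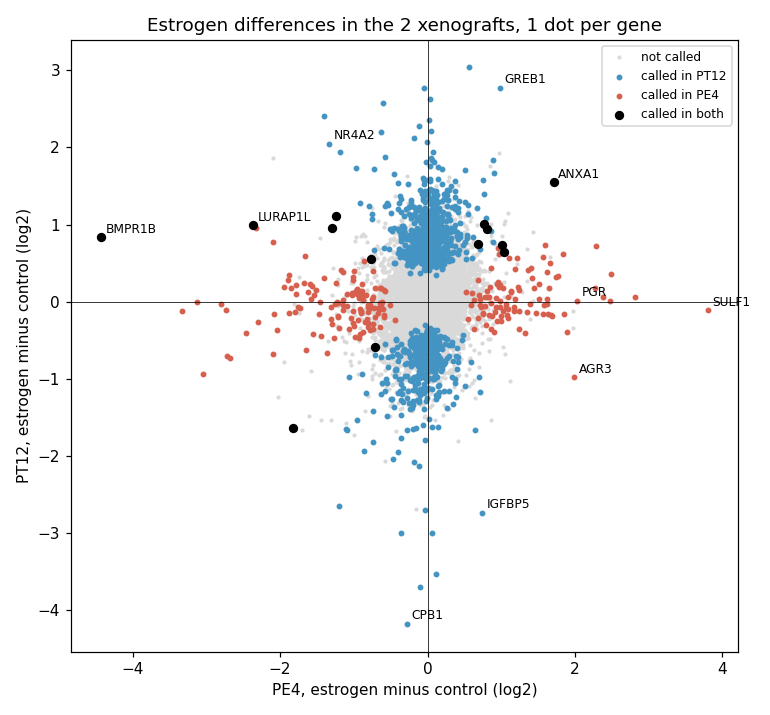
Log2 difference between estrogen and control in PE4 (horizontal axis) and in PT12 (vertical axis), with 1 dot per gene for all 17958 genes and the called genes coloured by xenograft. Most called genes lie along either axis, and 13 dots mark genes called in both, 8 in the same and 5 in opposite directions.

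Withdrawal of estrogen in PT12 (3 arrays) was compared with estrogen treatment (4 arrays). NR4A2 fell from 7.37 ± 0.82 to 5.63 ± 0.41 (mean ± SD), a difference of -1.74 ± 0.33 (adjusted p = 0.0319). MGAM, an intestinal maltase gene, fell from 5.81 ± 0.33 to 4.14 ± 0.34 (-1.67 ± 0.18, adjusted p = 7.58e-04), and RASGRP1 fell by 1.81 on the log2 scale (SE 0.41, adjusted p = 0.0387). The other large falls were ARHGAP11B (-1.98), TMPO (-1.68), FREM2 (-1.66), RBM24 (-1.65), TFPI2 (-1.64), SGO1 (-1.62), which protects chromosome cohesion in division, and GGA2 (-1.48). TMEM212 (1.80), DPPA2 (1.37), SIGLEC9 (1.14), FOLH1 (1.07), PPP4R4 (1.04), TEKT1 (0.97), TRIM51 (0.95), CLCA2 (0.87), SLC44A5 (0.82) and MIR129-1 (0.82) rose most. GREB1 differed by -2.06 ± 0.69 (adjusted p = 0.08), TFF1 by -1.72 ± 0.72 (0.144), CCND1 by -1.20 ± 0.37 (0.0644), MKI67 by -0.98 ± 0.35 (0.0933), MYC by -0.58 ± 0.25 (0.154), ESR1 by -0.33 ± 0.25 (0.386), CXCL12 by -0.24 ± 0.28 (0.587), KRT5 by 0.19 ± 0.13 (0.362) and PGR by 0.12 ± 0.22 (0.743). The withdrawal arrays were uneven: GREB1 stood at 8.32 in array 3 against 4.64 and 5.1 in the others, TFF1 at 10.71 against 7.21 and 7.58, and MKI67 at 6.49 against 4.7 and 4.83.

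Lists of dividing cells, DNA replication and mitosis, were lower after withdrawal. Camera had called neither of them for estrogen against control in PT12 or PE4. On mitosis, PT12 estrogen arrays stood at 0.0489 to 0.43 and controls at -0.563 to 0.317. DNA replication had a median of -0.54 over 34 members and mitosis of -0.72 over 33 (camera adjusted p = 3.32e-10 for each, adjusted p = 0.233 with an estimated correlation). In the first, 7 members fell, among them TYMS (-1.46 ± 0.34), DSCC1 (-1.29 ± 0.30), MCM7 (-1.21 ± 0.29) and MCM4 (-1.16 ± 0.24), and 17 when adjusted over the list alone. In the second, PRC1 (-1.15 ± 0.31) and AURKB (-0.72 ± 0.17) fell, and 15 when adjusted over the list alone. The estrogen-induced list was lower (median -0.54, camera adjusted p = 3.31e-07, adjusted p = 0.233 with an estimated correlation). RASGRP1, CA12 (-1.44 ± 0.31), PRSS23 (-1.09 ± 0.19) and RET (-1.03 ± 0.25) fell, and 14 members when adjusted over the list alone. Fatty acid synthesis was lower (median -0.48, camera adjusted p = 5.26e-05, adjusted p = 0.233 with an estimated correlation), with 5 of 18 members down, such as FADS2 (-1.99 ± 0.50) and SCD (-1.53 ± 0.35), and 7 when adjusted over the list alone. Luminal identity (median -0.76, camera adjusted p = 7.35e-06, adjusted p = 0.233 with an estimated correlation) and cholesterol synthesis (median -0.43, camera adjusted p = 0.00116, adjusted p = 0.233 with an estimated correlation) were lower without a member past the test over all genes in limma. When adjusted over each list alone, 7 and 9 members fell. Hypoxia was lower (median -0.44, camera adjusted p = 1.45e-05, adjusted p = 0.245 with an estimated correlation), with PDK1 (-1.18 ± 0.29) past the test and 9 when adjusted over the list alone. Withdrawal array 3 lay within the estrogen arrays on mitosis (0.107 against 0.0489 to 0.43), estrogen-induced genes (0.0527 against -0.0262 to 0.387), hypoxia (0.0776 against -0.102 to 0.189), fatty acid synthesis (-0.118 against -0.18 to 0.376) and luminal identity (-0.308 against -0.532 to 0.606). These falls rest on withdrawal arrays 1 and 2. Array 3 lay barely below the estrogen arrays on DNA replication (-0.107 against -0.0986 to 0.215) and cholesterol synthesis (-0.0646 against -0.0571 to 0.229). Those falls too rest mainly on arrays 1 and 2 (-0.686 and -0.779, then -0.402 and -0.501). Markers of other cell types, which include those of the mouse host if its RNA binds the probes, were slightly higher: B lymphocyte (median 0.25, camera adjusted p = 7.26e-04), endothelial (0.21, 0.00363), muscle (0.18, 0.0103), macrophage (0.16, 0.0109) and fibroblast lists (0.18, 0.028), with an adjusted p = 0.233 to 0.289 with an estimated correlation. Most markers of other cell types were dim in PE4 controls (80 of 102 under the lowest array median). That count was not made in PT12, so it does not show that they were dim there. The 25th percentile of an array lay at 3.62 to 3.758 after withdrawal and 3.523 to 3.635 with estrogen. These small rises were not separated from a shift of dim signal.

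In all, 661 genes passed between withdrawal and estrogen, 213 higher and 448 lower, against 178 and 768 with centred arrays and 163 and 120 with quantile normalization. Of the 1020 genes called for estrogen, 211 moved back after withdrawal (197 that had risen and 14 that had fallen), against 20.3 expected if the calls were independent. Both comparisons share the estrogen arrays: across genes they correlated with r = -0.711 (covariance -0.107), and simulated data without effects gave -0.427 (covariance -0.0165) and no shared call. Data without effects hold few calls to share, so the lack of a shared call has no bearing on the count of 211. The count of 661 was 4 without estrogen array 1, 3 without estrogen array 2, 5 without withdrawal array 1 or 2, 1031 and 1987 without estrogen arrays 3 and 4, and 3081 without withdrawal array 3. That of 211 was 58 and 127 without control arrays 2 and 3, 3 without estrogen array 1 or 2, 553 without estrogen array 3, 4 and 3 without withdrawal arrays 1 and 2, and 923 without withdrawal array 3. With the interquartile range as a covariate both counts were 0 in limma, where 298 genes had an unadjusted p under 0.05. GREB1 then differed by 0.31. The groups do not overlap in interquartile range (2.28 to 2.51 after withdrawal, 2.57 to 2.88 with estrogen). The covariate can therefore not be separated from the treatment here. With that covariate the list medians turned above 0 for estrogen-induced genes (0.00585), fatty acid synthesis (0.0653) and cholesterol synthesis (0.0536) and below 0 for endothelial (-0.0245) and muscle markers (-0.00323), none past the test. Over all alternatives the medians ranged from -0.761 to -0.103 for DNA replication and from -1.09 to -0.353 for mitosis. They ranged from -1.08 to -0.129 for luminal identity and from -0.671 to -0.0522 for hypoxia. Endothelial and muscle markers of withdrawal array 3 also lay within the estrogen arrays, as did endothelial markers of withdrawal array 2 (0.157 against -0.102 to 0.172).

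Set against untreated PT12 controls (3 arrays each), withdrawal left few differences past the test. TUSC3 was higher, at 7.25 ± 0.55 against 4.95 ± 0.53 (2.31 ± 0.31, adjusted p = 0.00513), and ANXA1 at 11.23 ± 0.34 against 9.58 ± 0.15 (1.65 ± 0.25, adjusted p = 0.0152). MIR23A (1.12) and BPIFA3 (0.63) were also higher. STC1, a secreted glycoprotein hormone gene (-1.55 ± 0.21, adjusted p = 0.00513), the prostaglandin receptor gene PTGER2 (-1.44 ± 0.15, adjusted p = 5.67e-04), KRT222 (-1.32) and PDCD5 (-0.89) were lower. The DNA replication list was lower (median -0.53, camera adjusted p = 1.14e-10, adjusted p = 0.456 with an estimated correlation), with 20 of 34 members lower when adjusted over the list alone. Mitosis (median -0.59, camera adjusted p = 1.72e-07, adjusted p = 0.541 with an estimated correlation) and ribosome biogenesis (-0.27, 1.59e-04, adjusted p = 0.456 with an estimated correlation) were lower too. No member of the DNA replication, mitosis and ribosome biogenesis lists passed over all genes in limma. On the mitosis list control array 3 stood apart, at -0.563 from the mean of all arrays against 0.317 and 0.288 in the other controls, and withdrawal array 3 stood at 0.107 against -0.791 and -0.839 in the other withdrawal arrays. Withdrawal array 3 also lay within the controls on DNA replication (-0.107 against -0.279 to 0.163) and ribosome biogenesis (-0.16 against -0.253 to 0.0541). No gene of the fixed panel passed in limma, and TFF1 differed by -0.87 ± 0.77 (adjusted p = 0.651). These 8 genes, 4 higher and 4 lower (26 and 10 with quantile normalization), became 4 without control array 2 or withdrawal array 1, 151 without control array 3 and 316 without withdrawal array 3. With the replicate block the count was also 4.

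Tamoxifen in PT12 (3 arrays) was compared with estrogen (4 arrays). COLEC12, a scavenger receptor gene, rose from 5.36 ± 0.23 to 7.20 ± 0.15 (mean ± SD), a difference of 1.84 ± 0.23 (adjusted p = 0.00103). STC1 rose from 6.81 ± 0.12 to 8.36 ± 0.09 (1.55 ± 0.19, adjusted p = 9.20e-04), and the lipid transporter gene ABCA4 by 1.49 ± 0.17 (adjusted p = 4.55e-04). ELOVL2, which elongates polyunsaturated fatty acids, fell from 7.60 ± 0.44 to 5.08 ± 0.57 (-2.52 ± 0.42, adjusted p = 0.0169), and RAB31 from 7.69 ± 0.47 to 5.52 ± 0.15 (-2.17 ± 0.36, adjusted p = 0.0169). GP2 (1.55), IL1RAPL2 (1.53), TIMP4 (1.16), NAV3 (1.10), ABCC12 (1.09), MECOM (0.94) and ENTREP1 (0.69) also rose. PPM1K (-1.84), MGAM (-1.61), SGK3 (-1.52), PRSS23 (-1.21), ABCC2 (-1.11), DCAF10 (-0.83) and AUNIP (-0.59) also fell. GREB1 differed by -2.30 ± 0.69 (adjusted p = 0.405), TFF1 by -1.69 ± 0.72 (0.71), MKI67 by -1.13 ± 0.35 (0.436) and CCND1 by -0.92 ± 0.37 (0.676), with arrays of the groups that did not overlap but without passing the test. ESR1 (-0.07 ± 0.25, adjusted p = 0.999), CXCL12 (-0.34 ± 0.28, 0.978), MYC (-0.31 ± 0.25, 0.981), KRT5 (0.01 ± 0.13, 0.999) and PGR (0.01 ± 0.22, 1.000) did not pass either.

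The mitosis list was lower with tamoxifen (median -0.71, camera adjusted p = 3.82e-27, adjusted p = 0.133 with an estimated correlation), with 20 of 33 members lower when adjusted over the list alone. DNA replication was lower (median -0.42, camera adjusted p = 5.89e-17, adjusted p = 0.133 with an estimated correlation), with 4 of 34 members lower when adjusted over the list alone, and so was ribosome biogenesis (-0.23, 5.31e-08, adjusted p = 0.133 with an estimated correlation). The estrogen-induced list was lower (median -0.29, camera adjusted p = 3.20e-08, adjusted p = 0.17 with an estimated correlation), with ELOVL2, SGK3 and PRSS23 past the test and 7 lower and 2 higher when adjusted over the list alone. Genes that estrogen is known to lower were higher (median 0.40 over 18 members, camera adjusted p = 3.72e-06, adjusted p = 0.17 with an estimated correlation). Of them, 5 rose when adjusted over the list alone. On this list PT12 estrogen arrays stood at -0.0568 to 0.364 and controls at -0.108 to 0.267. Tamoxifen was higher on it than controls too (median 0.33, camera adjusted p = 0.00323). For estrogen against control in PT12, camera called neither this list nor mitosis, DNA replication or ribosome biogenesis. The hypoxia list was lower (median -0.22, camera adjusted p = 5.56e-04, adjusted p = 0.585 with an estimated correlation). Apart from the estrogen-induced list, no member of these lists passed over all genes in limma. Tamoxifen array 3 lay within the estrogen arrays on hypoxia (0.0131 against -0.102 to 0.189), and array 2 on the estrogen-lowered list (0.285 against -0.0568 to 0.364). In all, 19 genes passed, 10 higher and 9 lower (18 and 10 with quantile normalization). The count was 32 without estrogen array 2, 12 without estrogen array 3 and 10 without tamoxifen array 3, and 526 with array weights. Of the 1020 genes called for estrogen, 6 moved back with tamoxifen, RAB31, MGAM, PRSS23 and ABCC2 downward and STC1 and IL1RAPL2 upward, against 0.533 expected if the calls were independent (10 without estrogen array 2). Both comparisons share the estrogen arrays: across genes r was -0.386 (covariance -0.0375), and simulated data without effects gave -0.429 (covariance -0.0165) and no shared call. The lack of a shared call has no bearing on the count of 6, since data without effects hold few calls to share. With the estrogen arrays divided between the comparisons, r lay between -0.419 and 0.32, so its sign depended on the arrays.

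**Figure D3:**
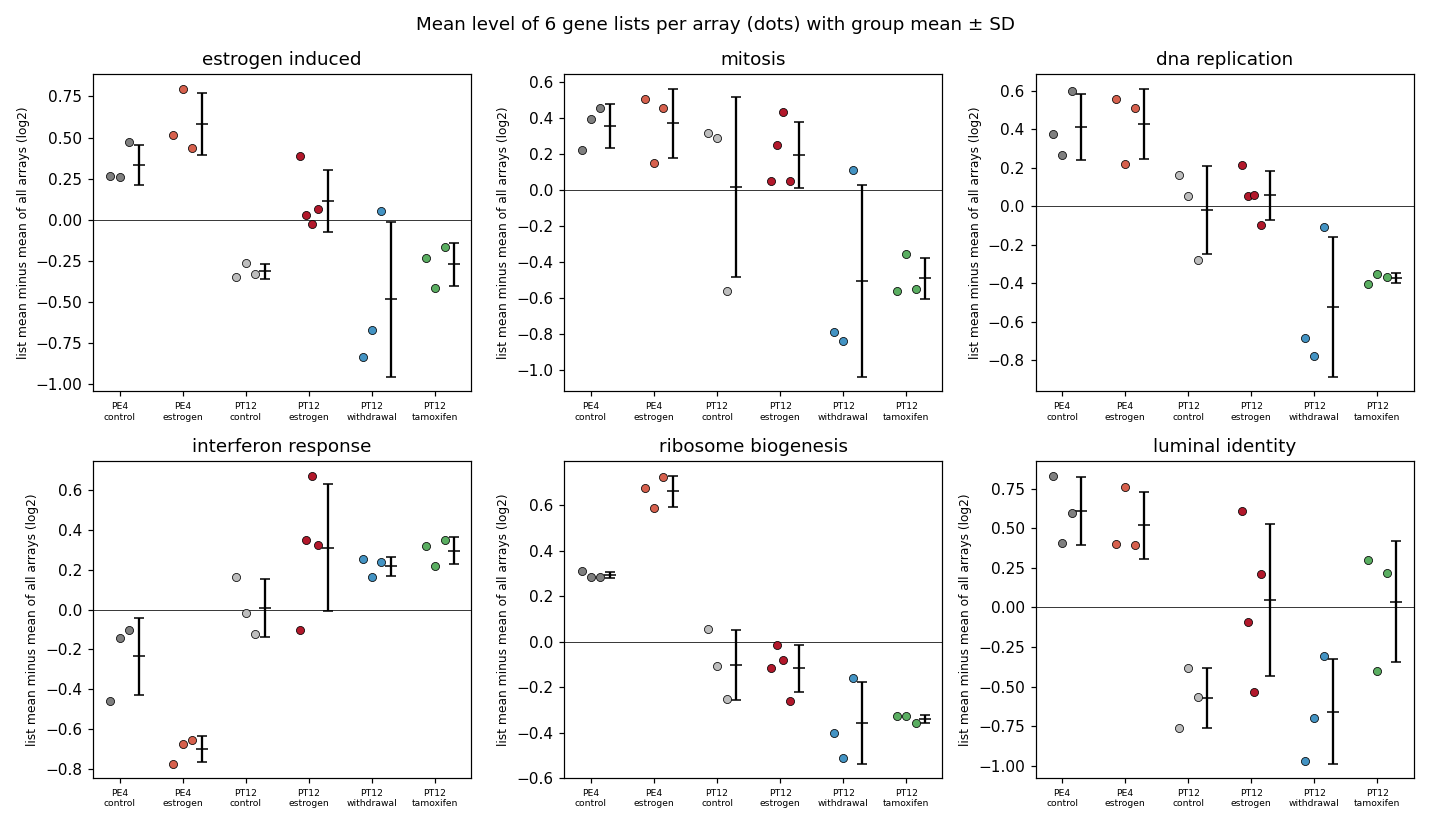
Mean log2 level of 6 gene lists in each array (dots) minus its mean over all arrays, by group, with the group mean and SD beside them. The mitosis list lies lower in the tamoxifen arrays than in each estrogen array of PT12. The third withdrawal array stands above the other withdrawal arrays in the estrogen-induced, mitosis and DNA replication lists, and the interferon response list is lower in each PE4 estrogen array than in each PE4 control.

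Against untreated controls (3 arrays each), tamoxifen-treated PT12 had LRP1B at 7.99 ± 0.60 against 5.19 ± 0.18, a rise of 2.80 ± 0.40 (adjusted p = 0.00272), and ABCA4 at 7.29 ± 0.26 against 5.19 ± 0.31 (2.11 ± 0.18, adjusted p = 2.57e-05). The immediate early gene IER3 (2.63), AOX1 (2.49), GASK1B (2.40), RGL2 (2.29), TUSC3 (2.09), GLRA3 (1.97), IFI6 (1.86) and CREG1 (1.86) rose. ELOVL2 fell from 7.93 ± 0.38 to 5.08 ± 0.57 (-2.84 ± 0.44, adjusted p = 0.0042). BRINP3 (-3.78), PPFIA2 (-2.72), IL20 (-2.51), SNORD14E (-2.28), TPRG1 (-2.08), PPM1K (-2.08), PPP4R4 (-1.92), SCARNA8 (-1.90) and ZNF415 (-1.89) fell. The luminal identity list was higher (median 0.56, camera adjusted p = 8.22e-04, adjusted p = 0.575 with an estimated correlation), with MLPH (1.71 ± 0.35) and ELF3 (1.65 ± 0.38) past the test, 2 also when adjusted over the list alone. On this list tamoxifen array 2 (-0.404) lay within the controls (-0.763 to -0.384), with 0.298 and 0.215 in arrays 1 and 3. The interferon response list was higher (median 0.25, camera adjusted p = 0.0108, adjusted p = 0.575 with an estimated correlation), with IFI6, IFI35, OAS1 and IRF9 past the test and 6 when adjusted over the list alone. The mitosis list was lower (median -0.52, camera adjusted p = 4.86e-06, adjusted p = 0.575 with an estimated correlation), with AURKA (-0.99 ± 0.27) past the test and 3 when adjusted over the list alone. Its mean level in control array 3 (-0.563) was as low as in the tamoxifen arrays (-0.563 to -0.36), so the difference rests on control arrays 1 and 2. No gene of the fixed panel passed in limma, and MKI67 differed by -0.99 ± 0.37 (adjusted p = 0.146). In all, 668 genes passed, 424 higher and 244 lower. Of these, 394 had also passed in the same direction with estrogen, against 20.1 expected if the calls were independent; the comparisons share the control arrays (r = 0.795 and covariance 0.118 across genes, 0.534 and 0.022 in simulated data without effects), and part of the excess may come from them. The count of 668 was 367 and 109 without control arrays 1 and 2, 79 and 196 without tamoxifen arrays 1 and 3, and 136 with the interquartile range as a covariate. That of 394 was 253 and 46 without control arrays 1 and 2, 237 and 684 without estrogen arrays 1 and 3, 50 and 133 without tamoxifen arrays 1 and 3, and 2 with that covariate.

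Tamoxifen and withdrawal (3 arrays each) were also set side by side. ABCA4 was higher with tamoxifen, at 7.29 ± 0.26 against 5.24 ± 0.08 (2.05 ± 0.18, adjusted p = 3.91e-05), STC1 by 1.82 ± 0.21 (adjusted p = 8.62e-04) and IER3 by 2.78 ± 0.49 (adjusted p = 0.0148). AOX1 (2.31), GGA2 (1.91), SELENOM (1.82), SLC34A2 (1.72), ATP6V0B (1.67), SLC27A2 (1.66) and PPIF (1.66) were also higher. PPM1K (-1.65 ± 0.28, adjusted p = 0.0129) was the gene with the largest fall, before SIGLEC9 (-1.04), GRB14 (-0.94), ANKRD13C-DT (-0.78), LINC02724 (-0.75), OR52N2 (-0.75), SIGLEC11 (-0.71), MIR195 (-0.71), NANOGNB (-0.69) and GSTA5 (-0.68). The luminal identity list was higher with tamoxifen (median 0.74, camera adjusted p = 8.60e-06, adjusted p = 0.541 with an estimated correlation), with 1 of 19 members past the test when adjusted over the list alone. The groups overlapped on it, since tamoxifen array 2 (-0.404) lay below withdrawal array 3 (-0.308). Over the alternatives the median of this list ranged from 0.214 to 1.02. No gene of the fixed panel passed in limma, and CCND1 differed by 0.28 ± 0.39 (adjusted p = 0.74). In all, 184 genes passed, 155 higher and 29 lower. The count was 21, 32 and 1600 without withdrawal arrays 1, 2 and 3, 19, 283 and 18 without tamoxifen arrays 1, 2 and 3, and 1 with the interquartile range as a covariate. The groups do not overlap in interquartile range (2.53 to 2.76 with tamoxifen, 2.28 to 2.51 after withdrawal), so that covariate cannot be separated from them.

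The untreated xenografts (3 arrays each) differed widely. TCN1, a vitamin B12 binding protein gene, stood at 10.96 ± 0.17 in PT12 and 3.25 ± 0.29 in PE4 (mean ± SD), a difference of 7.71 ± 0.51 (adjusted p = 9.16e-09). PVALB (6.88), CPB1 (6.48), CEACAM6 (6.42), PON3 (5.88), GRIK1-AS2 (5.66), ANXA1 (5.47), POF1B (5.31), AGR3 (5.28) and ANXA3 (4.73) were also higher in PT12. GRPR, the receptor of gastrin-releasing peptide, stood at 3.28 ± 0.12 in PT12 and 9.48 ± 0.11 in PE4 (-6.21 ± 0.13, adjusted p = 4.36e-15). RAB31 (-6.01), SLITRK6 (-5.87), AGTR1 (-5.36), BMPR1B (-5.24), AMIGO2 (-5.18), MKX (-4.74), CYP2B7P (-4.51), AARD (-4.50) and DOCK10 (-4.43) were lower in PT12. Of the fixed panel, these genes were lower in PT12: ESR1 by -1.32 ± 0.27 (adjusted p = 7.12e-04), PGR by -2.40 ± 0.24 (1.03e-06), GREB1 by -3.48 ± 0.74 (0.00106), MYC by -2.76 ± 0.27 (8.33e-07) and CCND1 by -1.99 ± 0.39 (6.14e-04). The luminal identity list was lower (median -1.22, camera adjusted p = 0.00119, adjusted p = 0.63 with an estimated correlation), with 16 of 19 members lower, FOXA1 (-2.74 ± 0.46) and CLDN3 (-2.22 ± 0.51) among them, 1 higher, and the same numbers when adjusted over the list alone. The hypoxia list was lower (median -1.27, camera adjusted p = 4.81e-05, adjusted p = 0.63 with an estimated correlation), with 16 of 25 members down, such as ENO2 (-3.36 ± 0.17) and NDRG1 (-2.95 ± 0.56), the same number when adjusted over the list alone. Of 49 estrogen-induced genes, 27 were lower and 6 higher, among the latter AGR2 (3.47 ± 0.28) and AGR3, with 28 and 6 when adjusted over the list alone (median -0.74, camera adjusted p = 0.00172, adjusted p = 0.63 with an estimated correlation). The insulin-like growth factor list was lower (median -0.68, camera adjusted p = 0.0348, adjusted p = 0.63 with an estimated correlation), with 8 of 13 members down, IGF1R (-4.27 ± 0.47) and IRS1 (-4.11 ± 0.23) among them, and 1 up, the same numbers when adjusted over the list alone. TFF1 (1.12 ± 0.77, adjusted p = 0.234), CXCL12 (-0.39 ± 0.30, 0.277), MKI67 (-0.53 ± 0.37, 0.241) and KRT5 (0.29 ± 0.14, 0.104) did not pass. In all, 8878 genes passed, 4575 higher and 4303 lower in PT12, 1288 of them at least 2-fold higher and 2188 at least 2-fold lower, and the median of all genes was 0.12 higher in PT12. With the interquartile range as a covariate the list medians were -0.317 for luminal identity, -0.545 for hypoxia and -0.362 for estrogen-induced genes (camera adjusted p = 0.73, 0.0844 and 0.741), and -0.358 for insulin-like growth factors (adjusted p = 0.0262). The count was 821 with that covariate, a measure on which the arrays of the xenografts do not overlap.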

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

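The tests of the position of withdrawal array 3, of random lists for that array, both tests of the PT12 estrogen count, the tests of other cell types and of averaged arrays for the interferon list, and the splits for calls shared by estrogen and tamoxifen were chosen only after the result was seen.

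The effect of estrogen differed between the xenografts for 209 genes by a test of the difference itself (PT12 minus PE4, log2). BMPR1B (5.26), SERPINA3 (3.95), TMEM45A (3.82), NR4A2 (3.39) and LURAP1L (3.36) had the largest positive differences, and SULF1 (-3.91), TARP (-3.66), IGFBP5 (-3.48), AGR3 (-2.97), ZNF804B (-2.75) and PGR (-2.02) negative ones. BMPR1B started far lower in PT12 controls than in PE4 controls. SERPINA3 differed by -2.10 ± 0.57 in PE4 and by 1.86 ± 0.54 in PT12, neither past the test alone (limma adjusted p = 0.103 and 0.051). Lists with a different estrogen effect were interferon response (median 0.717), luminal identity (0.642), antigen presentation (0.469), hypoxia (0.44), BCL2 family apoptosis (0.314), muscle (-0.16) and ribosome biogenesis (-0.374), none of which passed with an estimated correlation (adjusted p = 0.196 to 0.809). Of 100 splits that mixed estrogen and control arrays within each xenograft, 3 gave at least as many genes, the labels included, a share under 0.05. The highest other count was 1274. Groupings that mix the treatments can thus call several times as many genes, which points to a structure among the arrays. The share therefore does not separate a different response to estrogen from that structure. For the lists, 24 of these splits gave at least the 7 lists called, up to 13, so chance is not excluded.

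Some arrays of the PT12 estrogen group stood far from the other 3. In array 1, ABCC12 was 3.51 (mean of the others 3.79), DPPA2 2.43 (2.63) and NAV3 3.91 (4.07). In array 3, MKI67 was 6.76 (6.17) and NR4A2 6.15 (7.78). In array 4, AGR3 was 7.39 (8.65), NANOGNB 3.4 (2.97) and SLC27A2 3.93 (4.51). These are 8 of 127 genes checked, near the share of about 1 in 20 that chance gives. Among the 14116 probe sets without a single gene name, 40 passed between estrogen and control in PE4 and 993 in PT12 with the limma test. These counts come from the fit of all probe sets. In the fit of genes, 235 and 1020 of 17958 passed, so in PT12 the share was no smaller among unnamed probe sets. Of the 993, 433 were higher with estrogen, against 625 of the 1020 genes. The cause was not tested.

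Withdrawal array 3 lay above withdrawal arrays 1 and 2 on the estrogen-induced list, by a mean of 0.806 (random lists of the same brightness -0.12 to 0.184, percentile 100), which argues against an unequal spread of signal as the whole cause. Over 1445 genes called for estrogen in a fit without the withdrawal arrays, its median position was 0.838 (control mean 0, estrogen mean 1), against 0.115 and 0.0795 for arrays 1 and 2, 0.758 to 1.26 for the estrogen arrays and 0.663 to 0.998 for the tamoxifen arrays. A mislabelled sample and an incomplete withdrawal would both give this and cannot be told apart, since no estrogen array stood out of place as a partner of a swap and an outside sample needs none. A lower share of human RNA in arrays 1 and 2 could also contribute: 46% of the 500 brightest genes were lower in them than in array 3, which met the bound set beforehand against it (under 75%), but that bound was wrong, because the 95th percentiles of the 3 arrays lie close together (8.88 to 8.94), so that normalization holds bright genes in place. This explanation therefore stays open, and the array was kept in all comparisons.

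The PT12 estrogen count of 1020 rests on an uneven set of arrays. Quantile normalization, which gives all arrays 1 distribution, kept 79.8% of the calls in the same direction. This argues against unequal distributions of the arrays as the whole cause. It cannot exclude shifts of single genes that go with the signal spread, since such shifts survive it. With the interquartile range as a covariate only 4 genes were called: GREB1 went from 2.77 to 1.28 and EGLN3 from 3.04 to 2.12, and the cause was not tested. The groups overlapped little in that range (2.463 to 2.595 in controls, 2.571 to 2.883 with estrogen). A structure among the arrays other than the groups may contribute, since 3 other splits of the 7 arrays called more genes, up to 2005 when control arrays 1 and 2 stood with estrogen arrays 2 and 3. The biological explanation, a response to estrogen, stays open and is not separated from that structure or from the signal spread.

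The lower interferon list in PE4 with estrogen (median -0.394) was weighed against 3 technical explanations. RNA from other cell types would lower their markers too, and the lowest median among their 8 lists was -0.0144, but 80 of these 102 markers lie under the lowest array median in PE4 controls and could hardly fall, so this explanation stays open. Averaging the very similar estrogen arrays 1 and 3 left a camera adjusted p of 5.59e-10 (1.32e-13 to 0.103 over the alternatives of this result). An unequal signal spread would move genes of the same brightness alike, but the median lay at percentile 0 of random lists (-0.0769 to 0.0846). A response of the tumor cells to estrogen may be the source and remains 1 hypothesis beside other cell types, since the list did not pass with an estimated correlation and the 6 arrays allow too few splits to exclude chance.

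Other splits of the same arrays gave the following. For PT12 estrogen against control, 4 of 35 splits called at least 1020 genes (highest other 2005) and 12 called at least the 6 lists (13). For withdrawal against estrogen 5 of 35 called at least 661 genes (2353) and 2 at least 16 lists (16). For tamoxifen against estrogen 3 of 35 called at least 19 genes (1043) and 9 at least 8 lists (13). Chance is not excluded for these counts of PT12. Splits that call several times the real count point to a structure among the PT12 arrays. For calls shared by both xenografts 1 of 100 splits, the real one, reached 8 (highest other 5). For calls moved back after withdrawal 2 of 100 reached 211 (779), for calls moved back with tamoxifen 4 of 100 reached 6 (1137), and for calls shared by estrogen and tamoxifen 1 of 100 reached 394 (313), shares under 0.05. Since the median split of 2 groups called 0 genes and could share none, these shares say that the labels call genes more than that the calls overlap. The 8 genes shared by both xenografts are close to the 6.49 expected if the calls were independent (6 against 3.59 for rises, 2 against 2.9 for falls). The calls thus show no clear overlap beyond that. Shared effects too small to be called are not excluded by it. Of the 235 genes called in PE4, 136 differed in the same direction in PT12. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In PE4 the real count was 235 and the highest other 5 (1 split as large; lists 4 and 9, with 5 splits as large). The values were, for withdrawal against control, 8 and 118 (2 splits; lists 5 and 11, 7 splits). They were 668 and 0 for tamoxifen against control (1 split; lists 11 and 11, 2 splits), 184 and 320 for tamoxifen against withdrawal (2 splits; lists 9 and 11, 4 splits), and 8878 and 0 for the untreated xenografts (1 split; lists 6 and 10, 9 splits).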

How the results depend on the processing

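The averaging of PE4 estrogen arrays 1 and 3, the interquartile range as a covariate, PT12 estrogen array 1 and withdrawal array 3 left out together, and all alternatives of the calls shared by estrogen and tamoxifen were chosen only after the data were seen. Of 7635 alternative values of named genes, 6144 kept the side of the threshold (78 of them, past it in neither fit, with the other sign), 1453 kept the direction and lost the call, 23 gained it and 15 reversed. Of 1428 values of gene lists, 1113 kept the call, 303 lost it and 12 reversed in the direction of camera, which ranks all genes and need not follow the sign of the median. The limits are the low number of arrays and, for dim genes such as PGR in PT12, signal near the low end of the arrays. The replicate block could not be fitted for the untreated xenografts, since the numbers lie within a xenograft. Unless a cause is given, the cause was not tested.

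Counts of called genes that moved by over 1.5 times are given by setting, with PT12 meant where no xenograft is named. With the replicate block, which leaves fewer residual degrees of freedom, they were 193 for estrogen against control, 186 for withdrawal against estrogen, 9 for tamoxifen against estrogen, 4 for withdrawal against control, 306 for tamoxifen against control, 18 for tamoxifen against withdrawal, 121 for the difference between xenografts, 2 for shared estrogen calls, 23 for calls moved back on withdrawal, 3 for calls moved back with tamoxifen and 111 for calls shared by estrogen and tamoxifen. With only the compared groups in the limma fit, arrays were fewer and the residual spread came from those groups alone. The median SD of genes within a group was 0.142 and 0.113 in PE4 control and estrogen. It was 0.207 and 0.241 in PT12 control and estrogen, so the shared spread of the main fit can be too small for PT12. How far each lowered the counts was not tested. The counts were then 155 for estrogen against control, 0 for withdrawal against estrogen (2929 at an unadjusted p under 0.05) and 0 for withdrawal against control (1738). They were 5 for tamoxifen against withdrawal, 0 for shared estrogen calls, 0 for calls moved back on withdrawal and 111 for calls shared by estrogen and tamoxifen. With trend and robust options they were 13 for withdrawal against control, 4 for shared estrogen calls and 11 for calls moved back with tamoxifen.

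With array weights they were 1043 for PE4 estrogen against control, 4660 for withdrawal against estrogen, 526 for tamoxifen against estrogen, 54 for withdrawal against control, 2160 for tamoxifen against control, 3204 for tamoxifen against withdrawal, 1128 for the difference between xenografts, 39 for shared estrogen calls, 780 and 75 for calls moved back on withdrawal and with tamoxifen, and 757 for calls shared by estrogen and tamoxifen. With centred arrays they were 307 for tamoxifen against withdrawal and 5 for shared estrogen calls. Quantile normalization gave 283 for withdrawal against estrogen, 36 for withdrawal against control, 66 for calls moved back on withdrawal and 10 for calls moved back with tamoxifen. Background subtraction gave 383, 39 and 127 for the first 3 of these. With dimmer genes left out, so with fewer genes tested, they were 102 for PE4 estrogen against control, 4 for withdrawal against control, 5589 for the untreated xenografts and 101 for the difference between xenografts. With all probe sets tested, so with more features, they were 2119 for estrogen against control, 1349 for withdrawal against estrogen, 85 for withdrawal against control, 1082 for tamoxifen against control, 388 for tamoxifen against withdrawal, 14494 for the untreated xenografts, 3 for shared estrogen calls, 401 for calls moved back on withdrawal and 707 for calls shared by estrogen and tamoxifen.

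With PE4 estrogen arrays 1 and 3 averaged, the difference between xenografts had 109 genes and 3 estrogen calls were shared. With estrogen array 1 and withdrawal array 3 left out, the counts were 2173 for withdrawal against estrogen, 59 for tamoxifen against estrogen, 373 for withdrawal against control, 1965 for tamoxifen against withdrawal, 406 for the difference between xenografts, and 547 and 28 for calls moved back on withdrawal and with tamoxifen. With the interquartile range as a covariate they were 4 for estrogen against control, 0 for withdrawal against estrogen (298 at an unadjusted p under 0.05 in limma), 5 for withdrawal against control, 136 for tamoxifen against control, 1 for tamoxifen against withdrawal, 821 for the untreated xenografts, 63 for the difference between xenografts, 0 for shared estrogen calls, 0 and 2 for calls moved back on withdrawal and with tamoxifen, and 2 for calls shared by estrogen and tamoxifen.

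All reversed values, for lists by the direction of camera, arose with that covariate, in comparisons whose groups do not overlap in interquartile range. For withdrawal against estrogen the reversed values were MCL1 0.04 and the medians of the lists BCL2 family apoptosis 0.0432, endothelial -0.0245, cholesterol synthesis 0.0536, fatty acid synthesis 0.0653, immediate early 0.0493, ribosome biogenesis 0.0498 and unfolded protein response 0.0922. For tamoxifen against withdrawal they were endothelial -0.0184, cholesterol synthesis -0.0433, fatty acid synthesis -0.0974, hypoxia -0.0623 and unfolded protein response -0.0343. In 6 further values the median turned sign as the call was lost: with the covariate estrogen-induced (0.00585) and muscle (-0.00323) for withdrawal against estrogen and immediate early (-0.021) for tamoxifen against withdrawal, with array weights estrogen-induced in PE4 (-0.0206) and BCL2 family apoptosis for withdrawal against estrogen (0.04), and the last without estrogen array 1 (0.0221). For the untreated xenografts, whose arrays do not overlap in interquartile range, they were CYP2B7P 0.34, BAK1 0.0619, MS4A1 -0.19, FCRLA -0.0896, FCRL1 -0.0839, TEK -0.19, TIE1 -0.0291, ALAS2 -0.16, ACTA2 0.10, CNN1 -0.0174, ERBB3 0.47, DDIT4 0.39, IER3 0.39 and JUN 0.34.

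With each array left out in turn, the counts ranged from 163 (without PE4 estrogen array 3) to 197 in PE4, 189 (control array 2) to 1976 (estrogen array 3) for PT12 estrogen against control, 3 (estrogen array 2) to 3081 (withdrawal array 3) for withdrawal against estrogen. They ranged from 10 (tamoxifen array 3) to 32 (estrogen array 2) for tamoxifen against estrogen, 4 (control array 2) to 316 (withdrawal array 3) for withdrawal against control. The range was 79 (tamoxifen array 1) to 997 (control array 3) for tamoxifen against control, 18 (tamoxifen array 3) to 1600 (withdrawal array 3) for tamoxifen against withdrawal. It was 6888 to 8228 for the untreated xenografts and 104 (PE4 estrogen array 1) to 298 (PT12 estrogen array 3) for the difference between xenografts. The overlaps ranged from 3 to 16 for shared estrogen calls, 3 (estrogen array 1) to 923 (withdrawal array 3) for calls moved back on withdrawal, 4 to 10 for calls moved back with tamoxifen, and 46 (control array 2) to 684 (estrogen array 3) for calls shared by estrogen and tamoxifen. When the estrogen arrays were divided so that the comparisons did not share them, between 2 and 72 calls moved back on withdrawal (r from -0.684 to -0.141 across genes) and between 3 and 7 with tamoxifen (r from -0.419 to 0.32).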

Other observations

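In this part, the tests with the interquartile range as a covariate and the readings of array overlap on lists were chosen after the data were seen. After withdrawal in PT12, further lists were lower than with estrogen by camera: ribosome biogenesis (median -0.21, adjusted p = 0.00116, with POLR1A at -0.82 ± 0.19), unfolded protein response (-0.23, 0.0167), immediate early genes (-0.14, 0.0176, with NR4A2 as the called member) and BCL2 family apoptosis (-0.10, 0.0298, with MCL1 at -0.79 ± 0.20). Their adjusted p = 0.234, 0.368, 0.473 and 0.36 with an estimated correlation, and 1, 0, 3 and 3 members were lower when adjusted over the list alone. Withdrawal array 3 did not lie below the estrogen arrays on any of these lists (-0.16, 0.218, -0.0579 and -0.0302), and with the interquartile range as a covariate all 4 medians were above 0 (0.0498, 0.0922, 0.0493 and 0.0432). Against controls, the withdrawal group was lower on fatty acid synthesis (-0.23, 0.0123, adjusted p = 0.592 with an estimated correlation), although its array 3 (-0.118) lay above every control (-0.397 to -0.199), and higher on the B lymphocyte list (0.22, 0.00855, adjusted p = 0.456 with an estimated correlation). Tamoxifen against estrogen was lower on fatty acid synthesis (-0.18, 0.0255, adjusted p = 0.585 with an estimated correlation), where only array 2 (-0.419) lay below the estrogen arrays (-0.18 to 0.376), and higher on the androgen and glucocorticoid response list (0.10, 0.0332, adjusted p = 0.17 with an estimated correlation), with 1 member higher when adjusted over the list alone.

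Tamoxifen against control was higher on the estrogen-lowered list (median 0.33, camera adjusted p = 0.00323), where YPEL3 (1.27 ± 0.34) and CCNG2 (0.97 ± 0.15) rose, on hypoxia (0.32, 0.00323), where PDK1 rose (adjusted p = 0.0153), and on immediate early genes (0.14, 0.0196), where IER3, NR4A2 (1.76 ± 0.35) and DUSP1 (1.62 ± 0.39) rose. Antigen presentation (0.26, 0.0083), BCL2 family apoptosis (0.24, 0.0302) and unfolded protein response (0.20, 0.0196) were higher. DNA replication (-0.40, 3.05e-05), with PRIM1 (-0.89 ± 0.19) and MCM6 (-0.90 ± 0.23) down, and ribosome biogenesis (-0.17, 0.00135), with LYAR (-0.83 ± 0.22) and DKC1 (-0.76 ± 0.20) down, were lower. These lists had an adjusted p = 0.575 to 0.701 with an estimated correlation. On antigen presentation tamoxifen array 2 (-0.0532) lay within the controls (-0.318 to 0.0613). Tamoxifen against withdrawal was higher on the estrogen-lowered list (0.32, 0.00117), fatty acid synthesis (0.43, 0.0115), cholesterol synthesis (0.32, 0.0291), hypoxia (0.22, 0.0291), unfolded protein response (0.25, 0.0112) and immediate early genes (0.07, 0.0115). It was lower on B lymphocyte (-0.21, 0.015) and endothelial markers (-0.15, 0.015), with an adjusted p = 0.541 to 0.646 with an estimated correlation. Withdrawal array 3 lay above all tamoxifen arrays on hypoxia (0.0776 against -0.441 to 0.0131) and within them on fatty acid synthesis (-0.118), cholesterol synthesis (-0.0646), unfolded protein response (0.218) and immediate early genes (-0.0579). With the interquartile range as a covariate the medians of fatty acid synthesis, cholesterol synthesis, hypoxia, unfolded protein response and immediate early genes were below 0 (-0.0974, -0.0433, -0.0623, -0.0343 and -0.021).

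In untreated PT12 against PE4, fatty acid synthesis was lower (median -0.86, camera adjusted p = 0.00487), with 11 of 18 members down and 1 up, FASN (-2.52 ± 0.47) among them, and BCL2 family apoptosis was lower (-0.61, 0.042), with BCL2L11 (-1.56 ± 0.16) and BCL2 (-1.52 ± 0.24) among 7 of 15 members down and 2 up, each with an adjusted p = 0.63 with an estimated correlation. With the interquartile range as a covariate these medians were -0.0788 and -0.21 (camera adjusted p = 0.877 and 0.73). In the list of basal cytokeratins and related genes, with no call by camera in any comparison, KRT15 rose with estrogen in PT12 (1.24 ± 0.22, adjusted p = 0.0067) and fell on withdrawal (-0.91 ± 0.22, adjusted p = 0.0389), and ITGA6 rose with estrogen in PE4 (1.62 ± 0.37, adjusted p = 0.0379). The lists of adipocyte, erythroid and myoepithelial markers and of ERBB receptors and ligands had no call by camera in the 9 comparisons, with medians for estrogen in PE4 of 0.11, 0.05, 0.11 and 0.07 and in PT12 of 0.00, -0.04, 0.03 and 0.12. ERBB4 of the last list fell with estrogen in PT12 (-1.66 ± 0.44, adjusted p = 0.0371).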
